A study of Mus musculus with 20 samples.

How the data were processed

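Gene expression was measured in mouse embryonic fibroblasts (MEFs), cells grown out of mouse embryos, that had been cultured for 24 hours with serum of female C3H/HeN mice, an inbred strain. Per the labels, the serum came from non-irradiated mice (0 Gy) or from mice irradiated at 4 Gy (10 days) or 8 Gy (20 days), under a regime written as L/MDR that the labels do not expand. The labels do not say whether the days are the length of the exposure or the time until serum was taken; they are called durations here. Groups and replicate numbers (1 to 5) were taken from the sample titles, giving 4 groups of 5 arrays. Nothing in the labels says that replicates came from separate cultures or serum donors, so p-values measure only the spread between these arrays, which may be technical. Total RNA was labelled with Cy3 and hybridised to Agilent one-colour oligonucleotide microarrays, 1 sample per array.

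The deposited scanner files of the authors gave a processed intensity for each spot, a fluorescence intensity after background subtraction and spatial detrending within the array, with no scaling between arrays. Per the file headers these were extracted with Agilent Feature Extraction 10.5.1.1, while the submitters' processing notes name version 11.0. The deposited files also hold raw median intensities of spot and local background, and quality marks of another kind (0 or 1) for spots well above background, saturated or non-uniform. The authors' deposited table of the whole series holds log2 values: recomputation gave a log2 processed intensity minus the 75th percentile of the array, with low values floored and each probe centred on its median over the 10 arrays of 1 duration. Because of that centring, arrays of different durations were not compared in that table. Correlations of the recomputed values with that table were at least 0.992 on every array.

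Each array had 43379 spots of 41174 distinct non-control probes. Spots marked non-uniform or as population outliers (50 to 181 per array) were left out, no spot was saturated (0 on all arrays), and spots of 1 probe were averaged. The log2 processed intensity minus the 75th percentile of the array was used as the signal, so that all changes are relative to that percentile. Between 56.8% and 67.2% of probes (23391 to 27661) were well above background, and the 75th percentile lay between 731.37 and 1464.3 intensity units. By group it was 1316 ± 109 for control serum at 10 days, 1104 ± 102 for 4 Gy serum, 916 ± 134 for control serum at 20 days and 939 ± 57 for 8 Gy serum (mean ± SD, n = 5 arrays each). The number of arrays, not the number of probes, limits the precision of each comparison.

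Probes carried accessions but no gene names. Accessions were matched to gene symbols of the RefSeq annotation of GRCm38.p6, which named 24844 probes (17178 genes) and left 16330 without a name. A probe was tested if it was well above background on all 5 arrays of at least 1 group, which 26233 probes were. The probe with the highest mean signal stood for its gene and unnamed probes stood for themselves, giving 20226 genes tested, 12910 of them named; both kinds are called genes in the text.

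Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, in 1 fit with a mean for each of the 4 groups, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The comparisons were 4 Gy serum with control serum at 10 days, 8 Gy serum with control serum at 20 days, the difference between these responses, and the control groups of both durations. Log2 changes are given with standard errors of the limma fit (n = 5 arrays per group, unless fewer are stated because a spot was left out). Of 42 gene lists fixed before the data were examined, 41 had at least 5 tested members. They were tested with camera, which compares a list with all other genes, with the correlation between genes estimated from the data and adjustment over 82 tests (both durations). Beside each list stands the number of members past the threshold over all genes and the number when p-values were adjusted over the list alone. Camera with a preset correlation of 0.01 and fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes, were run as alternatives. Camera on the control groups and on the difference between responses was added after the data had been seen, with adjustment over the 41 lists of each.

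Genes named in the text were fixed by a rule before the data were examined: the 10 highest and 10 lowest log2 changes past the threshold in each comparison with irradiated serum (5 and 5 in the others), the members with the smallest p of lists with at least 3 members past the threshold, and 8 fixed examples (Cdkn1a, Mki67, Acta2, Col1a1, Il6, Ccl2, Fkbp5 and Hmgcs1). The lists described with examples were picked after the values had been seen; results of all 41 lists are counted. For a gene well above background on none of the 5 arrays of a group, the fold change is a lower bound, written "at least": the lower group was set to the weakest signal called well above background on each of its arrays, or to its own value where higher, and the adjusted p is that of the fit. The same was done for the difference between responses, where it made the difference smaller.

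Dose and duration changed together, and the durations were scanned on 2 different days, so neither dose, duration nor scan day can be separated, nor a change of cell preparation, of which the labels say nothing. The 20 arrays lay on 7 slides. At 10 days slide 1 held control arrays 1 to 4, slide 2 held control array 5 with irradiated arrays 1 and 2, and slide 3 held irradiated arrays 3 to 5. At 20 days slides 4 and 5 held only control arrays (1 to 3 and 4 to 5), and slides 6 and 7 only irradiated arrays (1 to 3 and 4 to 5). Slide was therefore also fitted as a random block (limma duplicateCorrelation), and at 10 days as a fixed block, which gives the change within slide 2.

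Alternatives fixed in advance were scaling to the array median, quantile normalisation, normexp background correction (offset 50), the deposited table, other filters on dim probes, tests by probe, only the 10 arrays of a duration, slide and replicate blocks, eBayes with trend and robust variance, array weights, a 2-fold threshold, other list tests and leaving out each array. Normexp used the median spot intensity, because the files give no mean. Leaving out slides, slide means, the mean of all probes of a gene and cyclic loess, which removes differences between arrays that depend on brightness, were added after the data had been seen. Splits of the arrays into other groups of 5 were drawn (100 of 126 for each comparison of 2 groups, and 100 of 31752 joint splits of both durations for the difference between responses and for the correlation) on the 19984 genes measured on every array. The lists were also compared with 10000 random lists of genes of the same brightness, drawn within 20 brightness bins. The procedure was tested on simulated data with the means and spreads of these arrays: of genes changed by 1 on the log2 scale it recovered 85.7% at 10 days and 83.1% at 20 days, with 8 false calls in each. With no group effect but the slide correlation measured at 10 days (0.574), the fit without slide called 471 to 605 genes at 10 days in 5 draws. At 20 days it called 0 to 4 with the correlation measured there (0.196), and 858 to 1029 with that of 10 days. The fit with slide as a random block called at most 1 gene in any of these draws. It was given the simulated correlation, so these draws do not show how it performs with a correlation estimated from the arrays. Slide shifts were drawn independently for each gene. Shifts shared by many genes could give other counts, so the simulated counts set no bound on what slides could give. Figures were drawn with matplotlib 3.10.9.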

Results

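Transcript levels were measured on 20 arrays of mouse embryonic fibroblasts that had been cultured with mouse serum, 5 arrays in each of 4 groups. Control serum came from non-irradiated mice of a 10-day and a 20-day set, 4 Gy serum from irradiated mice of the 10-day set and 8 Gy serum from irradiated mice of the 20-day set. Between 56.8% and 67.2% of the 41174 probes of an array were well above background, and 20226 genes were tested. Signals are log2 values relative to the 75th percentile of the array, and gene positions refer to GRCm38.p6.

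The first comparison asked how fibroblasts kept in serum of mice irradiated with 4 Gy (10-day set) differed from those kept in serum of non-irradiated mice. Saa1 (chromosome 7, 46740497 to 46743181), which encodes the acute phase protein serum amyloid A, had the highest fitted increase of the named genes, from −2.01 ± 1.28 to 0.30 ± 1.26 (SD, n = 5), a log2 change of 2.31 ± 0.63 (SE, adjusted p = 0.0361). The metallothionein gene Mt4 rose by 2.04 ± 0.40 (adjusted p = 0.0109) and Serpina3n, which encodes an acute phase protease inhibitor, by 1.57 ± 0.40 (adjusted p = 0.0275). Opn1mw (chromosome X, 74127466 to 74150756), a cone opsin gene, was at least 3.05-fold lower with 4 Gy serum (adjusted p = 0.0083). In all, 1208 of 20226 genes changed, 911 upward and 297 downward, and 364 of them by at least 2-fold (354 upward). The downward count was 594 under scaling to the array median, 537 with quantile normalisation and 179 with normexp. Of the called genes with another tested probe, 6 of 73 that rose and 3 of 76 that fell had it called too (median changes of the other probes 0.14 and −0.05, of the probes used 0.53 and −0.37).

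Among the other genes with large increases, Ly6f was at least 2.14-fold higher, the adenosine receptor gene Adora3 at least 1.67-fold and the receptor gene Gpr142 at least 1.41-fold. Log2 increases were 1.88 for Oacyl, 1.88 for the olfactory receptor gene Olfr1537, 1.80 for Ly6g6c, 1.74 for Cyp4f18, a cytochrome P450 gene, and 1.71 for Terc, the RNA component of telomerase. Among the genes that fell, the log2 change was −2.80 ± 0.53 for Dpf1 and −2.34 for Olfr1410 (each measured on 4 control arrays), −1.33 for the potassium channel gene Kcnc4, −0.93 for Pacs1 and −0.89 for Slc18a2, a vesicular monoamine transporter gene. Hoxc5, a homeobox gene, changed by −0.82, Lipg (endothelial lipase) by −0.76, the cold-inducible gene Rbm3 by −0.70 and the interferon-inducible gene Trim30a by −0.69. Another probe of Pacs1 gave −0.01 and another of Trim30a −0.85. Oacyl, Olfr1537 and Terc were well above background on 3 of the 5 control arrays and Mt4 on 4. With 4 Gy serum Slc18a2 was so on 1 array, Lipg on 3 and Trim30a on 4. None of the 8 fixed examples passed the test at 10 days: Cdkn1a (0.02), Mki67 (−0.07), Acta2 (0.06), Col1a1 (0.12), Il6 (0.25), Ccl2 (0.41), Fkbp5 (0.22) and Hmgcs1 (0.18) all had an adjusted p of at least 0.299.

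Of 24 acute phase and complement genes, 3 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.918 with an estimated correlation). Among them were Saa1, Serpina3n and the complement gene C1qb (0.60). Of 14 metallothionein and metal response genes, 3 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.918). Examples were Mt4 and the transferrin gene Trf (1.08). Of 13 epithelial markers 3 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.819). They included the keratin genes Krt17 (0.71) and Krt5 (0.92). Of 20 macrophage and myeloid markers 3 rose and 0 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.929). They included Clec4d (0.61) and Cd14 (0.36). Of 28 NF-kB and inflammatory cytokine genes 2 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.929): Nfkbie, an inhibitor of NF-kB, changed by 0.88 and Csf1, a macrophage growth factor, by −0.34. Of 37 interferon-stimulated genes 2 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.959), Ifit2 by 0.25 (another probe −0.05) and Trim30a by −0.69. Of 20 fatty acid synthesis genes 3 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.975). They included Acacb (0.84) and Elovl5 (0.31, another probe −0.24). Of 34 hypoxia and glycolysis genes 1 rose and 2 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.975), with Car9 at 0.68 and Vegfa, the angiogenic growth factor, at −0.35. Under the 4 other scalings 0 to 4 members of each of these lists passed in either direction. Camera called 0 of the 41 lists at 10 days (2 at unadjusted p under 0.05, smallest adjusted p = 0.819), against 6 with a preset correlation and 4 by fry.

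The called genes of the 10-day set differed between slides of the same group. Their median signed log2 change was 0.77 over all arrays and 0.08 within slide 2, the only slide with both groups. Irradiated arrays of slide 3 exceeded those of slide 2 by 0.52. Control array 5, the only control array of slide 2, exceeded the control arrays of slide 1 by 0.37. Of the genes named as called, these had the opposite direction within slide 2: Saa1 (−1.10), Cyp4f18 (−0.27), Oacyl (−0.11), Trf (−0.06), Nfkbie (−0.04), Acacb (−0.04) and Lipg (0.05). Of the 911 genes called upward 58.5% kept their direction there (median 0.04, against 0.90 over all arrays), and of the 297 called downward 89.9% did (median signed change 0.19 against 0.44). With slide as a random block 1 gene passed (Opn1mw, adjusted p = 0.00753, at least 16.6-fold lower within slide 2, against 1 control array). With slide as a fixed block, which rests on the 1 control array of slide 2, 0 passed upward and 12 downward. Only 1 of these 12 was among the 1208 called genes, and 451 of 20224 genes had an unadjusted p under 0.05. Without single arrays the count lay between 219 (irradiated array 3) and 2109 (irradiated array 2).

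**Figure D1:**
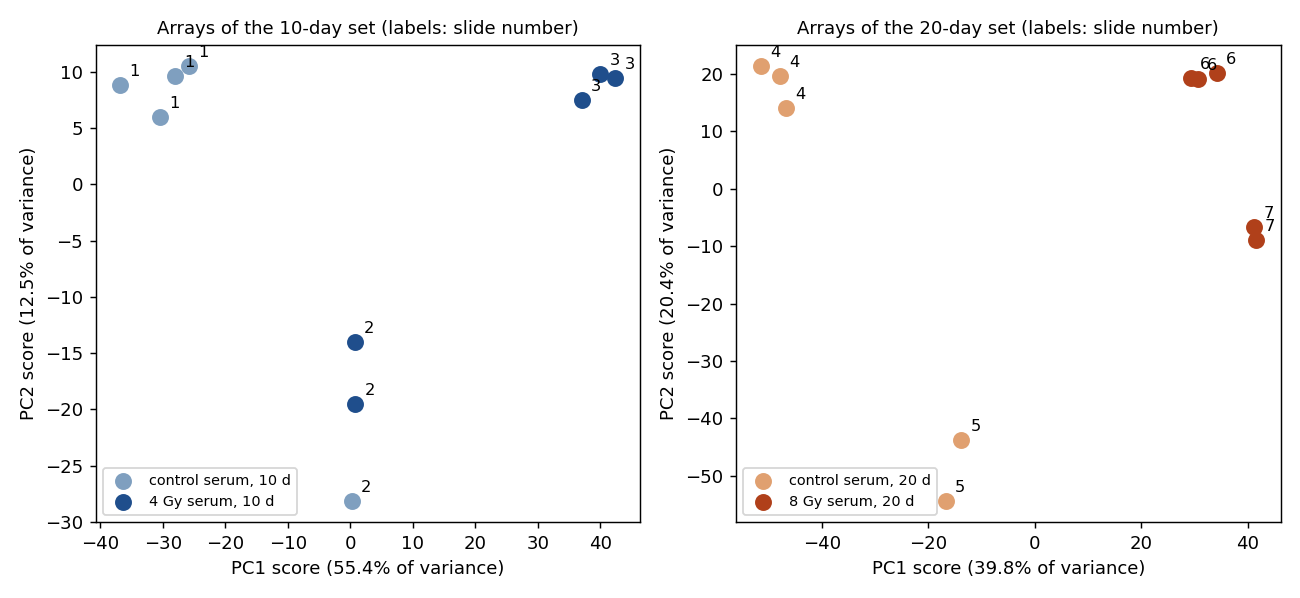
Principal components of the 10 arrays of each duration, with the first component score on the x axis and the second on the y axis (share of variance in percent); each point is an array, coloured by group and labelled with its slide. On the first component of the 10-day set, which held 55.4% of the variance, arrays of slide 1 lay between −36.8 and −25.8, those of slide 2 between 0.2 and 0.8 and those of slide 3 between 37.0 and 42.4.

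The second comparison asked the same question for serum of mice irradiated with 8 Gy (20-day set). Lars2 (chromosome 9, 123366927 to 123462675), which encodes mitochondrial leucyl-tRNA synthetase, rose 15.2-fold, from 5.02 ± 0.34 with control serum to 8.94 ± 0.10 with 8 Gy serum (SD, n = 5, adjusted p = 4.7e-14). Rn28s1, a 28S ribosomal RNA gene, rose from −4.57 ± 0.92 to 0.25 ± 0.36 (adjusted p = 1.11e-08), and Cdk5r2 (chromosome 1, 74855029 to 74857732), an activator of the kinase Cdk5, by a log2 change of 6.34 ± 0.61 (SE, adjusted p = 7.15e-07, measured on 3 arrays with 8 Gy serum). Probe sequences could not be mapped, so it was not checked whether the probes of Lars2 and Rn28s1 also bind other transcripts. Lcn2 (3.21 ± 0.85), Nfkb2 (0.74 ± 0.10) and Col4a2 (1.13 ± 0.16) rose, and Psmb2 (−0.88 ± 0.07) and Sdhc (−0.81 ± 0.08) fell. In all, 9311 genes changed, 3493 upward and 5818 downward, and 856 of them by at least 2-fold (656 upward, 200 downward). Of the called genes with another tested probe, 436 of 664 that rose and 684 of 1721 that fell had it called too (median changes of the other probes 0.54 and −0.12, of the probes used 0.54 and −0.46).

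Among the other genes with large increases, Syt10, a synaptotagmin gene, changed by 4.55, the transcription factor genes Tfap2e by 4.07, Foxq1 by 3.22 and Klf2 by 3.06, Rusc1 by 3.50 and the potassium channel gene Kcnh2 by 2.93. Another probe gave −0.04 for Rusc1 and −0.04 for Klf2. With slide as a random block the call of Lcn2, which encodes the iron-binding protein lipocalin 2, was lost (adjusted p = 0.0509). Slc4a7, a bicarbonate transporter gene, had the lowest fitted change of the named genes (−2.70), with other probes between −0.41 and 0.06, followed by Olfr1226 (−2.35). Ostn (osteocrin) changed by −1.76. Control arrays well above background numbered 4 for Cdk5r2 and Rn28s1 and 2 for Kcnh2, and Olfr1226 was so on 2 arrays with 8 Gy serum. The zinc transporter gene Slc39a2 was at least 2.76-fold lower, Olfr1215 at least 1.93-fold, Car10 at least 1.70-fold, Olfr1306 at least 1.29-fold, Olfr1232 at least 1.20-fold, the taste receptor gene Tas2r118 at least 1.18-fold and Olfr483 at least 1.17-fold. Of the fixed examples, Il6 changed by 0.89 (adjusted p = 0.0447), the proliferation marker Mki67 by −0.31 (adjusted p = 0.00874, another probe 0.43) and the sterol synthesis gene Hmgcs1 by −0.27 (adjusted p = 0.0351), and these 3 calls were lost with slide as a random block. Cdkn1a (0.02), Acta2 (−0.19), Col1a1 (0.06), Ccl2 (0.60) and Fkbp5 (0.30) did not pass.

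**Figure D2:**
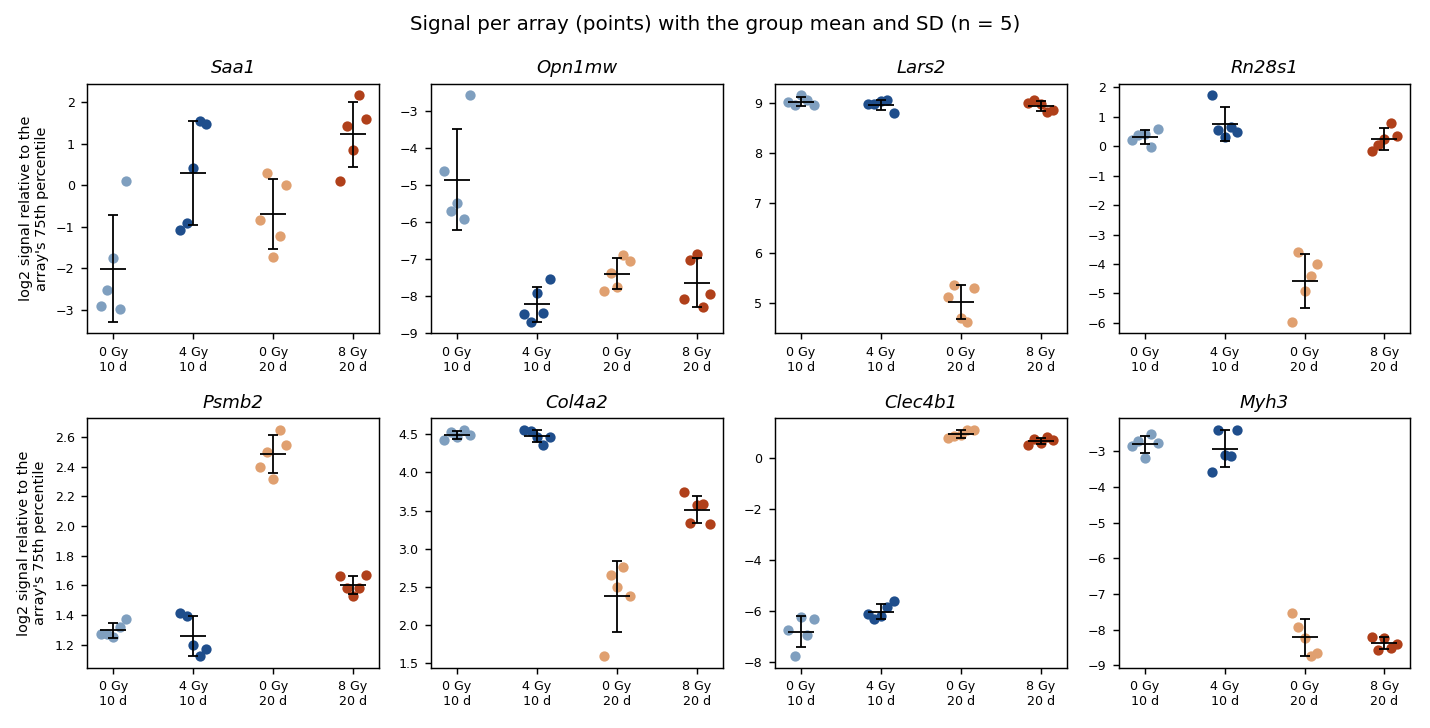
Signal of 8 genes in each group, as the log2 signal relative to the 75th percentile of the array (y axis) for each of the 4 groups (x axis); points are arrays, the horizontal mark is the mean and the bars are the SD (n = 5). Lars2 lay at 5.02 ± 0.34 with control serum at 20 days and at 9.03 ± 0.09, 8.97 ± 0.10 and 8.94 ± 0.10 in the other groups, while Clec4b1 and Myh3 separated the 10-day from the 20-day set.

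Of 28 NF-kB and inflammatory cytokine genes, 11 rose and 0 fell at 20 days (10 and 0 adjusted over the list alone, camera adjusted p = 0.929 with an estimated correlation), against 7 and 2 under scaling to the array median. Among those that rose were Nfkb2, which encodes an NF-kB subunit, and the chemokine gene Cxcl12 (0.70, measured on 4 control arrays). Of 24 acute phase and complement genes 12 rose and 2 fell (14 and 2 adjusted over the list alone, camera adjusted p = 0.929): the complement inhibitor gene Serping1 rose by 0.88 and the complement gene C2 fell by 0.67 (another probe 0.39). Of 36 collagen and extracellular matrix genes 10 rose and 4 fell (9 and 4 adjusted over the list alone, camera adjusted p = 0.929), against 6 and 9 under scaling to the array median and 19 and 2 under cyclic loess. Col4a2 and the proteoglycan gene Bgn (0.87) were among those that rose. Of 24 matrix proteases and inhibitors 3 rose and 7 fell (3 and 7 adjusted over the list alone, camera adjusted p = 0.975), against 7 and 4 under cyclic loess. The gelatinase gene Mmp2 rose by 1.02, and the metalloproteinase inhibitor gene Timp3 fell by 0.73. Of 28 secreted senescence-associated factors 7 rose and 5 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.975), against 5 and 8 under scaling to the array median and 14 and 2 under cyclic loess. Igfbp4, an IGF-binding protein gene, rose by 1.54 (another probe 1.53) and Tnfrsf11b (osteoprotegerin) fell by 0.63. Of 19 circadian clock genes 4 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.918), against 4 and 4 under scaling to the array median and 1 and 0 with normexp. The clock repressor genes Per3 (1.37, well above background on 1 control array) and Cry2 (0.47) rose.

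Of 38 oxidative phosphorylation genes, 1 rose and 22 fell (1 and 23 adjusted over the list alone, camera adjusted p = 0.918 with an estimated correlation), but under cyclic loess 4 rose and 9 fell and the list's median of −0.30 was 0.00. Ndufb5 (−0.93, measured on 4 control arrays) of complex I and Sdhc of complex II were among those that fell. Of 31 proteasome genes 2 rose and 19 fell (2 and 19 adjusted over the list alone, camera adjusted p = 0.918), with a median of −0.36, which was −0.11 under cyclic loess (5 rose, 11 fell). The core subunit genes Psmb2 and Psma3 (−0.74) fell. Of 39 cytosolic ribosomal protein genes 2 rose and 17 fell (3 and 17 adjusted over the list alone, camera adjusted p = 0.975), but 14 rose and 6 fell under cyclic loess. Rps19 (−1.05) was among those that fell. Of 34 DNA replication genes 6 rose and 16 fell (6 and 16 adjusted over the list alone, camera adjusted p = 0.929), against 2 and 21 under scaling to the array median. The histone mRNA binding gene Slbp (−0.55) and the cyclin gene Ccne2 (−1.08) were among those that fell. Of 33 G2/M and mitosis genes 3 rose and 12 fell (3 and 12 adjusted over the list alone, camera adjusted p = 0.975), against 3 and 6 with quantile normalisation. Birc5 (−0.79) and Cenpe (−0.62, other probes 0.01 to 0.29) fell. Of 30 p53 target genes 3 rose and 11 fell (3 and 11 adjusted over the list alone, camera adjusted p = 0.959), against 2 and 17 under scaling to the array median and 4 and 7 under cyclic loess. Perp changed by −0.66 and Sesn2 by 0.58. Of 18 histone genes 4 rose and 7 fell (4 and 7 adjusted over the list alone, camera adjusted p = 0.975), and the linker histone genes H1f4 (1.5) and H1f5 (1.06) were among those that rose.

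Of 31 NRF2 and oxidative stress genes 2 rose and 15 fell (2 and 16 adjusted over the list alone, camera adjusted p = 0.929), against 5 and 7 under cyclic loess. The glutathione transferase gene Gsta4 (−0.73) and Me1 (−0.41) fell. Of 23 ER stress genes 1 rose and 12 fell (2 and 12 adjusted over the list alone, camera adjusted p = 0.918), against 2 and 8 with quantile normalisation. The chaperone gene Canx (−0.44) and Herpud1 (−0.75) fell. Of 27 immediate early genes 2 rose and 9 fell (2 and 8 adjusted over the list alone, camera adjusted p = 0.975), and the median of −0.16 was 0.01 under cyclic loess. Klf2 rose and the proto-oncogene Myc fell by 0.89 (other probes −0.46 to −0.38). Of 37 interferon-stimulated genes 3 rose and 9 fell (3 and 9 adjusted over the list alone, camera adjusted p = 0.975). The double-stranded RNA sensor gene Eif2ak2 (−0.75) and Ifit2 (−0.38, another probe 1.16) fell. Of 17 adipocyte markers 2 rose and 6 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.975), the lipase gene Lipe at 0.95 and Acsl1 at −0.64 (other probes 0.21 to 0.52). Of 20 macrophage and myeloid markers 0 rose and 6 fell (0 and 5 adjusted over the list alone, camera adjusted p = 0.975), against 4 and 5 with quantile normalisation. They included Ptprc (−0.61, another probe 0.00), which encodes the leukocyte antigen CD45, and Tyrobp (−0.72). These macrophage markers were higher in control cultures of the 20-day set than in those of the 10-day set, by a median of 4.26 on the log2 scale.

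Camera called 0 of the 41 lists at 20 days (0 at unadjusted p under 0.05, smallest adjusted p = 0.918). With a preset correlation it called 4, oxidative phosphorylation (adjusted p = 0.00885) and proteasome genes (0.0112) downward and acute phase and NF-kB genes (0.0121 each) upward, and fry called 19 (3 upward, 16 downward). With slide as a random block 5912 genes passed (2121 upward, 3791 downward), and on slide means, 2 against 2, 4 passed. Each slide of the 20-day set held 1 group only, so no change within a slide could be given.

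**Figure D3:**
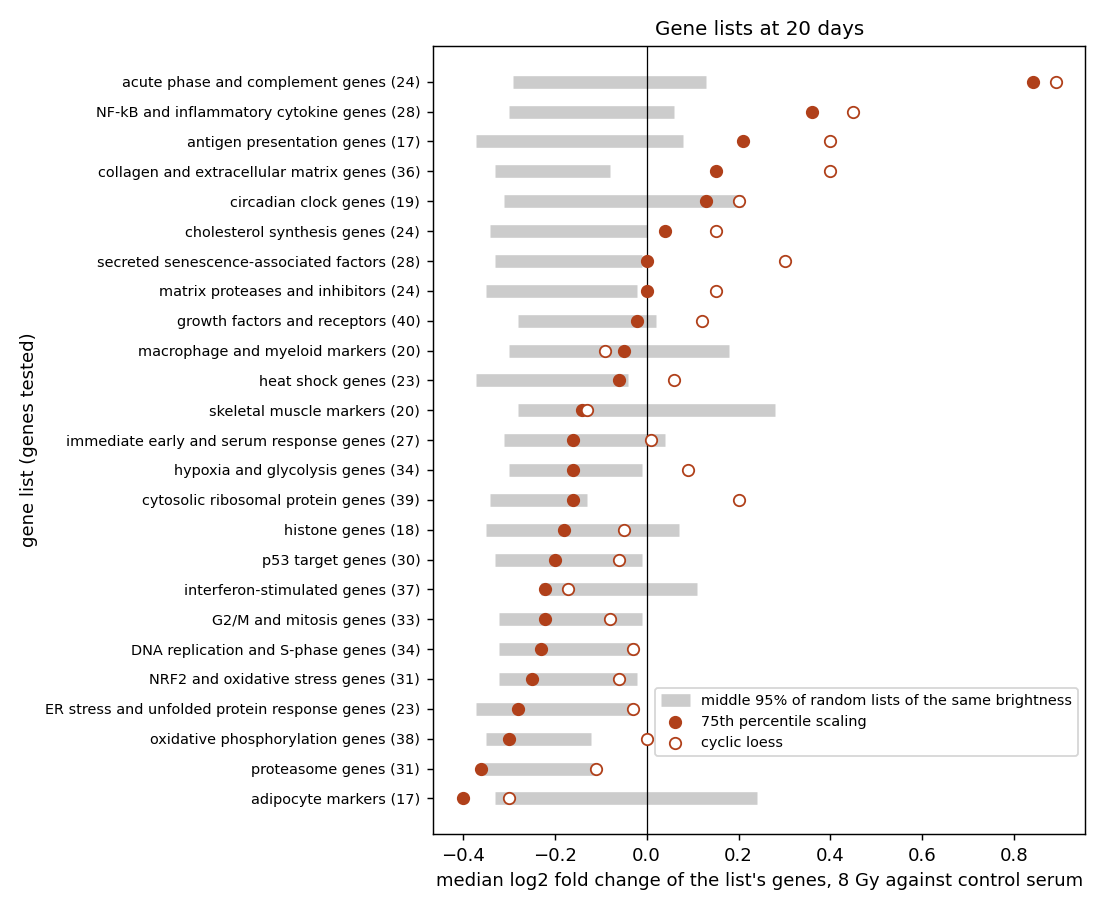
Median log2 fold change, 8 Gy against control serum at 20 days (x axis), of the genes of each described list (y axis, number of genes tested in brackets), with scaling to the 75th percentile (filled points) and with cyclic loess (open points); grey bars span the middle 95% of random lists of the same brightness. NF-kB genes lay at 0.36 and acute phase genes at 0.84, above their bars. The bars do not allow for correlation between the genes of a list. Oxidative phosphorylation genes lay at −0.30 within their bar and at 0.00 under cyclic loess. Ribosomal protein genes lay at −0.16 and 0.20.

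The responses at 10 and 20 days were then compared with each other. The genes with the highest excess of the 20-day over the 10-day response were Cdk5r2 (log2 difference 6.0 ± 0.81, SE), Syt10 (5.17), Rn28s1 (4.39), Lars2 (3.98 ± 0.17) and Tfap2e (3.72), with the probes of Rn28s1 and Lars2 unchecked as above. For each of these genes every control array of the 20-day set lay below all other arrays. Lars2 lay at 4.62 to 5.36 on these control arrays and at 8.79 to 9.16 on the others. Cdk5r2 lay at 1.34 to 2.28 with 8 Gy serum, below all arrays of the 10-day set (3.17 to 4.59). Among the genes with the lowest fitted differences were the olfactory receptor gene Olfr1226 (−3.46) and Terc (−2.83), which rose at 10 days. The ratio of the responses was at least 3.57-fold lower at 20 days for the homeobox gene Dmbx1. It was 5.75-fold lower for Olfr74 and 4.77-fold for Olfr635, and none of these genes was well above background with 8 Gy serum. The values of Olfr74 and Olfr635 are not lower bounds, since dim control arrays of the 10-day set were not raised. On array 1 they lay at −6.44 and −6.90, where the weakest signal called well above background was −5.97. By limma 6914 genes responded differently (2469 upward, 4445 downward), 3622 with slide as a random block. Of 457 genes called at both durations, 165 changed in the same direction (87 upward, 78 downward), while 222 rose at 10 days and fell at 20 days and 70 did the opposite. Independent calls would give 157.3 upward and 85.4 downward at both, and 262.1 and 51.3 in opposite directions. Across all genes, which are not independent replicates, the log2 changes at 10 and 20 days had a Pearson r of 0.009 and a Spearman rho of −0.005. Dose, duration and scan day differed together between these responses, and the labels do not say whether both sets used the same preparation of fibroblasts. Of 5 sex-linked transcripts, 4 were higher and 1 lower in control cultures of the 20-day than of the 10-day set. Their median log2 difference was 1.26 (camera adjusted p = 0.443 with an estimated correlation). The list holds the X-linked Xist beside Y-linked genes such as Kdm5d and Eif2s3y. These can move in opposite directions, so the joint median and a test of 1 direction cannot decide whether they differ. With irradiated serum at 20 days 0 of the 5 transcripts rose and 2 fell. Macrophage markers also differed between the control groups: all 20 tested were higher in the 20-day set, as given below. Whether the cells themselves, their serum or the arrays gave this was not tested. Whether the cells differed between control and irradiated groups was not tested either.

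The control groups of both durations, neither of them given serum of irradiated mice, were compared to see how far the sets differed. Clec4b1 (chromosome 6, 123049962 to 123071555), a C-type lectin gene of myeloid cells, was 214-fold higher in control cultures of the 20-day set (−6.80 ± 0.62 against 0.94 ± 0.15, SD, n = 5, limma adjusted p = 5.74e-16, well above background on 1 of the 5 arrays of the 10-day set), and the related Clec4a2 was 121-fold higher (another probe gave a log2 change of 7.29). Dcstamp, needed for fusion of osteoclasts, was at least 95.4-fold higher, Fxyd2 at least 54.1-fold and the lipid droplet gene Cidec at least 39.7-fold. Lower in the 20-day set were Cdk5r2 (−8.13), Syt10 (−7.47), Arid5b (−5.81, measured on 4 arrays of the 10-day set, other probes −2.46 to 0.69), Rusc1 (−5.41, another probe −0.60) and the embryonic myosin gene Myh3 (chromosome 11, 67078273 to 67102291), which was at least 9.49-fold lower. By limma 13422 genes differed (7473 higher and 5949 lower in the 20-day set), 11038 with slide as a random block.

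All 20 macrophage and myeloid markers tested were higher in the control cultures of the 20-day set (median log2 difference 4.26, camera adjusted p = 0.0479 with an estimated correlation), under each of the 4 other scalings too. Of 20 skeletal muscle markers 15 were lower and 2 higher (median −1.36, or −0.39 with normexp, camera adjusted p = 0.0479). Of 36 collagen and extracellular matrix genes 29 were lower and 3 higher (median −0.92, camera adjusted p = 0.0734), of 31 proteasome genes 24 were higher and 1 lower (median 0.86, or 0.43 under cyclic loess, camera adjusted p = 0.0734), and of 38 oxidative phosphorylation genes 33 were higher and 1 lower (median 0.83, or 0.39 under cyclic loess, camera adjusted p = 0.0734). Adjusted over the list alone, the counts of these 5 lists were the same. Camera called 2 of the 41 lists in this comparison and 0 for the difference between responses (2 at unadjusted p under 0.05, smallest adjusted p = 0.566), against 22 and 0 with a preset correlation. The control groups were also hybridised to different slides and scanned on different days.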

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

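The tests of slides, brightness, probes and groups on the genes called at 10 days, on the oxidative phosphorylation and proteasome genes at 20 days and on the genes at least 2-fold higher at 20 days were chosen only after these results had been seen; the splits of the arrays were fixed before the data were examined.

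At 10 days 1208 genes changed, of which 911 rose. Signal close to the background is argued against as the whole cause, since 4.93% of the genes well above background on all 20 arrays were called, against 5.97% of all genes tested, but 10.6% of the dimmest 10% of genes rose and 1% of the brightest 10%, and signals of single probes may account for part, with 9 of 149 called genes having another probe called in the same direction (median signed change 0.09, against 0.40 for the probes used). A difference between slides fits the values and is a candidate explanation: the median signed change of the called genes was 0.77 over all arrays but 0.08 within slide 2, where both groups lay side by side (0.04 of 0.90 for genes called upward, 0.19 of 0.44 for those called downward). An effect of 4 Gy serum stays open as well, because only 3 arrays of slide 2, which also went into the calls, compare the groups without a change of slide. Of 100 splits of the 10 arrays, drawn from 126, only the real one gave as many genes (1202 of the 19984 genes measured on every array). That argues against chance for arrays exchanged one by one, but chance was not excluded for slides. The next split, with 908, put irradiated array 2 in the place of control array 5 beside the 4 arrays of slide 1. The same exchange with irradiated array 1, also of slide 2, was not among the splits drawn. With slide as a random block 1 gene passed.

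At 20 days 22 of 38 oxidative phosphorylation genes and 19 of 31 proteasome genes fell. Signals of single probes stay open, since 6 of the 41 genes that fell had another tested probe, and 2 of these 6 had it called too (median 0.23 downward, against 0.37 for the probes used). A change that depends on brightness may account for the fall: the members' joint median of −0.31 lay inside the middle 95% of 10000 random lists of the same brightness (−0.32 to −0.16), and cyclic loess brought it to −0.07. The median change of all genes ran from −0.03 in the dimmest 10% of genes to −0.26 in the brightest 10%. A fall of these genes with 8 Gy serum was not excluded, since their median lay at percentile 4.82 of these random lists. Both lists also lay higher in control cultures of the 20-day set than in those of the 10-day set. Their medians there were 0.83 for oxidative phosphorylation and 0.86 for proteasome genes, and less under cyclic loess, as given above. Whether control arrays of the 20-day set standing apart account for the fall was not tested.

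At 20 days 656 genes were at least 2-fold higher with 8 Gy serum. Single probes are argued against as the whole cause by 44 of 66 genes with another probe that was also called upward, although the other probes changed less (median 0.57 against 1.23). A difference between slides stays open: over all genes the median absolute gap was 0.24 between both control slides and 0.14 between both irradiated slides, against 0.33 to 0.39 between slides of different groups, and the gaps in these genes (0.19 and 0.00, against 1.28) decide little, since they were picked for their gap between the groups. What fits the values is that the control arrays of the 20-day set stood apart: for these genes the irradiated groups of 20 and 10 days differed by a median of −0.10 (quartiles −0.61 and 0.44), and the control groups by −1.38 (quartiles −1.98 and −0.92), which did not hold for the 200 genes at least 2-fold lower (−0.80 and 0.79). That may reflect a property of the control cultures, of their serum or of a step shared by both control slides, and an effect of 8 Gy serum that brought these genes to the level of the 10-day set stays open too. Of all arrays, the control arrays of slide 4 had the fewest probes well above background (56.81% to 59.95%). They also had the most spots left out as outliers (154 to 181). Those of slide 5 did not (64.06% and 62.28%, 113 and 50 spots). Whether array quality played a part was not tested.

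At 20 days only the real one of 100 splits gave as many genes (9207, highest other 1882). The same held between the control groups (13275, highest other 5963). That argues against chance in both for arrays exchanged one by one, though only 100 of the 126 possible splits were drawn. Chance was not excluded for slides, since with 2 slides per group at 20 days they are too few for such splits, and slide means gave 4 genes. For the difference between responses the real split also gave the most genes (6854, highest other 5254). These splits relabelled both durations at once, so a response at 20 days alone could give that. Chance was therefore not excluded for the difference itself. The correlation of the responses was as large in 94 of 100 splits (0.004 on these genes, highest other 0.415), so chance is not excluded for it. Camera called 0 lists, which 100 of 100 splits reach whatever they hold, so the splits decide nothing there (highest other 2 at 10 days and 1 at 20 days).

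By a test of the difference itself, 6914 genes responded differently at 20 and 10 days. Among them were Cdk5r2 (6.0), Syt10 (5.17), Rn28s1 (4.39), Lars2 (3.98), Tfap2e (3.72), Olfr1226 (−3.46) and Terc (−2.83), as log2 differences. For Cdk5r2, Syt10, Rn28s1, Lars2 and Tfap2e every control array of the 20-day set lay below all other arrays. The ratio was at least 3.57-fold lower at 20 days for Dmbx1. It was 5.75- and 4.77-fold lower for Olfr74 and Olfr635, which are not lower bounds, since dim control arrays of the 10-day set were not raised. Of the 42 genes named for 10 days 24 responded differently, and of the 77 named for 20 days 68 did.

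For 22 genes 1 array stood far from the other 4 of its group (gap to the nearest over the range above 0.71), in 281 groups tested, where chance gives about 14.1. In control cultures of the 10-day set these were array 5 for Cdk5r2 (4.46, mean of the others 3.32), Tfap2e (5.91, others 4.64), Cyp4f18 (−4.69, others −5.67) and Nfkbie (−1.47, others −1.95), array 2 for Cd14 (−1.90) and array 3 for Slc18a2 (−6.40). With 4 Gy serum they were array 1 for Rn28s1 (1.74, others 0.50) and array 5 for Lars2 (8.79, others 9.01). In control cultures of the 20-day set they were array 1 for Psma3 (5.36, others 4.85), Myc (2.34), Gsta4 (1.49) and Fxyd2 (−0.37), array 2 for Ccne2 (−1.25), H2-M3 (1.14) and Ifit2 (−0.26), array 3 for Olfr1215 (−6.72) and array 5 for Hmgcs1 (4.64). With 8 Gy serum they were array 1 for Me1 (1.92), array 2 for Olfr483 (−7.17), array 3 for Slc39a2 (−7.45, others −6.24) and array 4 for Olfr1306 (−6.70) and Grem1 (1.46).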

How the results depend on the processing

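Cyclic loess, leaving out slides, slide means, the mean of all probes and the random slide block within a duration were chosen only after the results had been seen. The limits included the slides, single arrays, the weighting of arrays, the scaling and the brightness of the probes. What dims a probe limits its fold change, and 16521 of the 20226 genes were well above background on all arrays.

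The 10-day count of 1208 became 786 on genes well above background on all arrays (fewer genes tested), 2576 with only the 10 arrays of the duration, 11192 with array weights and 364 with a 2-fold threshold. Slide as a random block gave 1 gene (0 within the duration) and as a fixed block 12, of which 1 was among the 1208. Leaving out slide 1 leaves 1 control array, so no count is given for it. Without slide 3, which leaves 2 irradiated arrays, the count was 0. So few arrays could give that by themselves, so it decides nothing about slide 3. Without slide 2, which leaves control arrays of slide 1 against irradiated arrays of slide 3, the count rose to 3754. No slide then holds both groups, and the cause of that rise was not tested. The 20-day count of 9311 became 5912 with the random block, 5111 with it within the duration, 856 with a 2-fold threshold and 4 with slide means (fewer samples), and the count for the difference between responses 3622 with the random block. With a preset correlation camera called 6 lists at 10 days and 4 at 20 days, and fry 4 and 19. Where no other cause is named, the cause was not tested.

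Leaving out each array gave 219 to 2109 genes at 10 days, 8549 to 9756 at 20 days, 6107 to 7794 for the difference between responses, 12770 to 13755 between the control groups, a correlation of −0.037 to 0.052, and 0 to 0 lists at both durations. The 10-day count was 540, 325, 510 and 677 without control arrays 1 to 4, and 2003, 2109, 219, 224 and 319 without irradiated arrays 1 to 5. The replicate numbers did not pair the arrays at 10 days (correlations 0.14, 0.18, −0.05, 0.00 and 0.19), and at 20 days they coincided with the slides (0.17, 0.14, 0.16, 0.23 and 0.41). With a replicate block the counts were 1642, 9535, 6989 and 9811, the correlation 0.010 and the lists called 0 and 0.

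Scaling to the array median moved the median change of all genes at 20 days from −0.09 to −0.24 and between the control groups from 0.07 to 0.20 (0.22 with normexp). The share of called genes that rose at 20 days was 37.5%, and 22.6% with that scaling; at 10 days it was 75.4%, 56.4% with it and 61.8% with quantile normalisation. Among counts by direction, genes lower at 10 days (297) became 594 with scaling to the array median, 537 with quantile normalisation, 179 with normexp and 134 with no filter on dim probes, and 555 without control array 1 of the 20-day set. Genes higher became 5409 at 20 days and 4007 for the difference between responses when counted by probe, and 2083 at 20 days without slide 6. Between the control groups 11814 were higher with no filter on dim probes and 3924 lower with a replicate block. The other total counts of genes under alternatives fixed in advance stayed within 1.5 times the value reported, and the correlation lay between −0.082 and 0.085.

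Changes reversed for Arid5b between the control groups (0.69 with the probe left by the stricter filter), for Acta2 at 20 days (0.21 with cyclic loess), and within slide 2 at 10 days for Saa1 (−1.10), Oacyl (−0.11), Cyp4f18 (−0.27), Lipg (0.05), Nfkbie (−0.04), Acacb (−0.04) and Trf (−0.06). Of 42 gene values at 10 days, 33 lost their call with slide as a random block, 8 (the fixed examples) had none to lose and only Opn1mw kept it. Of 77 at 20 days 4 lost it (Lcn2, Il6, Mki67 and Hmgcs1) and 5 had none, but with slide means 70 of the 77 lost it. With normexp 12 of the 42 and 13 of the 77 lost their call, with no filter on dim probes 15 and 2, with only the arrays of the duration 8 and 1, and over all arrays left out in turn 185 of 840 values at 10 days and 17 of 1540 at 20 days did.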

Other observations

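The lists described here and the comparison with cyclic loess were chosen only after the results had been seen.

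Of 17 antigen presentation genes, 6 rose and 3 fell with 8 Gy serum at 20 days (7 and 3 adjusted over the list alone, camera adjusted p = 0.936 with an estimated correlation), against 4 and 3 with scaling to the array median. The peptide transporter gene Tap1 rose by 0.84 and the class I gene H2-M3 fell by 0.73 (another probe −0.66). Of 24 cholesterol synthesis genes 8 rose and 7 fell (8 and 7 adjusted over the list alone, camera adjusted p = 0.975), against 8 and 1 with cyclic loess and 6 and 7 with scaling to the array median. The squalene synthase gene Fdft1 rose by 0.72. Of 34 hypoxia and glycolysis genes 5 rose and 14 fell (5 and 14 adjusted over the list alone, camera adjusted p = 0.975), against 11 and 8 with cyclic loess and 4 and 21 with scaling to the array median. The glycolytic enzyme genes Pkm (0.70) and Hk1 (0.74) rose. Of 40 growth factors and receptors 13 rose and 9 fell (14 and 9 adjusted over the list alone, camera adjusted p = 0.929), against 5 and 14 with scaling to the array median and 15 and 3 with cyclic loess. The bone morphogenetic protein gene Bmp6 (0.73) and the antagonist gene Grem1 (0.91) rose. Of 20 skeletal muscle markers 2 rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.975), against 1 and 5 with cyclic loess, Des (desmin) by 0.92 and Tnnc1 by −0.69. Of 23 heat shock genes 2 rose and 9 fell (2 and 9 adjusted over the list alone, camera adjusted p = 0.975), against 8 and 2 with cyclic loess. The co-chaperone gene Stip1 rose by 0.33 and Hspa4l fell by 0.66.

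The medians of acute phase, NF-kB and matrix genes at 20 days were 0.84, 0.36 and 0.15. They lay above the middle 95% of random lists of the same brightness (upper ends 0.13, 0.06 and −0.08). Other lists did so too, among them contractile (0.07, upper end −0.05) and antigen presentation genes (0.21, upper end 0.08). Adipocyte markers lay below (−0.40, lower end −0.33). Random lists do not allow for the correlation between genes of a list (0.332, 0.362 and 0.13 here). Their ranges may therefore be too narrow, and the excess decides little. With cyclic loess 16 NF-kB genes rose and 0 fell and 19 matrix genes rose and 2 fell, and camera gave adjusted p = 0.756 and 0.574 with an estimated correlation, against 0.00548 and 0.000869 with a preset one. Of the 36 matrix genes, 29 were lower in control cultures of the 20-day set than in those of the 10-day set.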
